A study of Mus musculus with 20 samples.

How the data were processed

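RNA from small intestinal crypts of C57BL/6 mice was measured in 20 libraries by bulk sequencing of the 3' ends of polyadenylated transcripts with unique molecular identifiers. Wild-type mice and mice lacking Xiap, which encodes an inhibitor of cell death, were either housed by genotype, called housed apart here, or co-housed for 4 weeks. The groups held 6 wild-type and 4 Xiap-/- mice housed apart, and 5 wild-type and 5 Xiap-/- co-housed mice, as the sample titles give them. The text on RNA extraction speaks of liver, while the other labels give crypts, and crypts were kept because the Paneth cell product Defa24 had a mean of 14.17 and the highest hepatocyte marker, Ttr, one of 4.11. The labels name neither the cage, nor the time of collection, nor the part of Xiap that was deleted.

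The values were deposited by the authors as normalized values on a log2 scale, between -3.88 and 16.30, for 23020 genes. Per the submitters' processing notes, DESeq2 1.18.1 and genome build GRCm38.p6 were used, and the transformation is not stated. Genes with little signal lie on a plateau near their own mean, and whether the transformation shrinks the differences of lowly expressed genes was not tested. Counts per library are not in the values, so the depth of each library is unknown, and no counting interval or floor is given. As a proxy for depth, the share of rare genes (mean below -3) standing above their own plateau (0.015 over the median across libraries) was computed for each library, together with the offset of the plateau.

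The deposited values were analysed as they stand, with no pseudocount, in R 4.3.3 with limma 3.58.1. A gene was tested if its mean over the 20 libraries was at least log2 of 10, which left 9521 genes. One model of the 4 group means was fitted to all 20 libraries (lmFit), with a trend of the variance on the mean and robust empirical Bayes moderation, leaving 16 residual degrees of freedom. The comparisons were the genotype difference in each housing, the housing difference in each genotype and the difference between the genotype differences. All tests are two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, with no threshold on size. The limma and permutation p-values rest on the spread between mice, taken as independent although the cages are not named. Those of camera, described below, also rest on the correlation taken between genes. Errors of differences are standard errors from the model, and errors of group means are standard deviations over mice. The Xiap transcript and the depth proxy were compared by exact permutation tests.

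The design, 30 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Of the lists, 22 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation, on ranks, and with fry. For each list the members past the threshold were counted over all genes and adjusted over the list alone. The genes named are the 10 largest rises and the 10 largest falls among those that passed (predicted genes without a common symbol are counted and may go unnamed). For each list they include the 4 passing members with the smallest p or, if none passed, the 2 members with the highest mean, some of which are not used here. Where fewer than 5 genes passed, the 5 with the smallest p are given. Xiap, Lyz1, Defa24, Ang4, Mmp7, Reg3b, Reg3g and Tnf are named where measured. Other genes are marked as chosen after their values were seen. Positions are from GENCODE M21 on GRCm38, in which 97.8% of the tested symbols were found. For 24 date-like gene names, turned into dates by a spreadsheet program, no gene is named.

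The model was tested on simulated data with the spread of these libraries, with 100 genes shifted by 0.5 and 100 shifted by 1 on the log2 scale. At the smaller shift it recovered 84 genes for genotype housed apart, 86 for genotype co-housed, 90 for housing in wild-type mice, 84 for housing in Xiap-/- mice and 44 for the interaction. At the larger shift it recovered 99, 95, 97, 98 and 95, with 7, 9, 12, 5 and 7 false calls. In these data genes varied independently, and each gene had 1 spread for all groups. In the real values the spread can differ between groups (SD of Reg3g 0.81 in wild-type mice housed apart and 0.12 in co-housed wild-type mice). Fewer genes also passed in the real comparisons than were shifted here, so the recovered counts do not give the power for the real differences. In simulated values of the same kind, camera with either correlation called a shift of 0.3 in all 18 tested Paneth cell products. The same shift was then added to residuals of the real libraries in shuffled order, which keeps the correlation between genes, in 20 draws per comparison, a test added after seeing the data. In the order above, the preset correlation called the list in 17, 19, 20, 19 and 18 draws and a mean of 5.75, 5.70, 5.35, 5.55 and 4.40 of the 21 lists with no shift. The estimated correlation called it in 1, 5, 6, 0 and 0 draws and a mean of 0.05 to 0.15 of the lists with no shift. At the preset correlation false list calls are thus frequent, and the estimated correlation misses most shifts of this size.

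The alternatives tried were no filter and a mean of at least 50, pseudocounts of 0.5 and 5, rescaling by trimmed means, array quality weights, the replicate number as a block, the groups compared alone, and each library left out in turn. A pseudocount of 1, ordinary empirical Bayes moderation, the depth proxy as a covariate, and a fit without the deepest and the shallowest library were added after seeing the data. Tests on recovered counts were left out because the values hold none, and a sex covariate was left out because all 20 libraries were from females.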

Results

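Gene expression was measured in small intestinal crypts, the epithelial pits that hold stem, Paneth, goblet and dividing cells, of 20 mice. The genotypes were compared in mice housed apart (6 wild-type, 4 Xiap-/-) and after 4 weeks in shared cages (5 and 5). Mice in shared cages can also exchange microbes, of which these data hold no measure. Epithelial transcripts were abundant. The highest means of the Paneth list were those of the alpha-defensins Defa24 (14.17, log2 scale as for all levels here) and Defa30 (13.43), and the goblet cell products Zg16 and Tff3 reached 12.80 and 12.10. Transcripts of absorptive cells were also present, with Fabp2 at 13.75 and Apoa1 at 13.48, as were those of T cells, with the granzyme Gzma at 9.16. Markers of other cell types were scarce. Above the minimum mean stood 4 of 14 B and plasma cell markers (highest Igha, 5.17), 4 of 18 myeloid and mast cell markers (Fcer1g, 5.56), 1 of 15 stromal markers (Vim, 4.08), 0 of 8 glial and neuronal markers by this filter, 1 of 14 acinar markers (Cela1, 4.90), 1 of 12 hepatocyte markers (Ttr, 4.11) and 1 of 6 blood markers (Hbb-bs, 4.36). The female transcript Xist had a mean of 9.60, and the highest Y-linked gene, Kdm5d, lay at -2.04.

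Depth is unknown, and its proxy differed between groups. The share of rare genes above their plateau was 17.1% ± 10.5 (SD, n = 4) in Xiap-/- mice housed apart, 7.71% ± 3.69 (n = 6) in wild-type mice housed apart, 8.74% ± 1.47 (n = 5) in co-housed wild-type mice and 8.77% ± 2.77 (n = 5) in co-housed Xiap-/- mice. The offset of the plateau differed between the genotypes housed apart (exact permutation p = 0.0238 over 210 splits, adjusted p = 0.0476 over 4 comparisons) and between the housings of Xiap-/- mice (exact permutation p = 0.0238 over 126 splits, adjusted p = 0.0476). It did not pass between the co-housed genotypes (exact permutation p = 0.905, adjusted p = 0.905) or the housings of wild-type mice (exact permutation p = 0.186, adjusted p = 0.248).

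**Figure D1:**
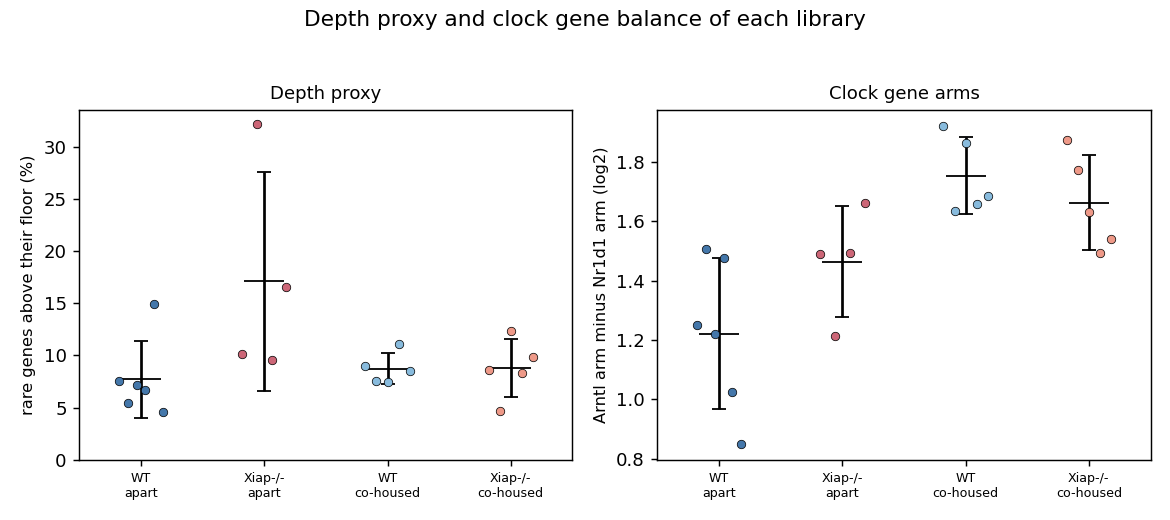
Depth proxy (left, share of rare genes above their plateau in percent) and clock gene balance (right, mean of Arntl, Clock and Npas2 minus mean of 6 genes of the opposite phase, log2) of each library. Points are mice, and bars are the group mean and SD. The deepest library by this proxy, Xiap-/- housed apart replicate 2, stands at 32.1%.

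The Xiap transcript itself (chromosome X, 42059679 to 42109656) had a level of 6.81 ± 0.17 (SD, n = 6) in wild-type and 6.38 ± 0.10 (n = 4) in Xiap-/- mice housed apart, and all 4 Xiap-/- values lay below all 6 wild-type values. The difference of -0.43 gave an exact permutation p of 0.00476, the smallest that 210 splits allow. Over all genes in limma, it did not pass (adjusted p = 0.0599). In co-housed mice the levels were 6.67 ± 0.20 (n = 5) and 6.62 ± 0.22 (n = 5), a difference of -0.05 (exact permutation p = 0.683). Reads from the 3' end can lie outside the deleted part of the gene, so a remaining transcript does not tell the genotype of a mouse.

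In mice housed apart, Xiap-/- crypts had more transcript of Sco2, Reg3a, Aqp8 and Ces1d, among others, and less of Gpx2, Pim1 and Pigr. Of these, only Aqp8, Ces1d and Pim1 passed whichever of the 20 libraries was left out. The comparison asks whether crypts of the genotypes differ when each lives with its own kind. Of 9521 genes, 28 were higher and 15 lower in Xiap-/- mice by limma, with differences of 0.35 to 1.12 in size. Sco2, a factor for assembly of cytochrome c oxidase (chromosome 15, 89371637 to 89373846), rose most, by 1.12 ± 0.19 (SE; adjusted p = 0.0164), from 7.10 ± 0.29 (SD, n = 6) to 8.22 ± 0.32 (n = 4). The water channel Aqp8 (chromosome 7, 123462291 to 123468004) rose by 1.00 ± 0.13 (adjusted p = 8.01e-05), from 3.95 ± 0.23 to 4.95 ± 0.33. For each of these genes all 4 Xiap-/- values lay above all 6 wild-type values.

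The carboxylesterase Ces1d (chromosome 8, 93166068 to 93197838) rose by 0.70 ± 0.09 (limma adjusted p = 8.01e-05), from 4.01 ± 0.12 to 4.72 ± 0.16, again without overlap. Aadac, a deacetylase of lipids and drugs (chromosome 3, 60025717 to 60040160), rose by 0.83 ± 0.14 (adjusted p = 0.00472). The antimicrobial lectin Reg3a (chromosome 6, 78380709 to 78383827) rose by 1.04 ± 0.22 (adjusted p = 0.0440), from 8.33 ± 0.54 to 9.38 ± 0.20, although wild-type replicate 5, at 9.29, lay within the Xiap-/- range. The glutathione transferase Gsta1 rose by 0.91 ± 0.19, the serum- and glucocorticoid-regulated kinase Sgk1 by 0.82 ± 0.18, the retinaldehyde dehydrogenase Aldh1a1 by 0.71 ± 0.16, the secreted lectin Reg4 by 0.69 ± 0.14 and the sulfurtransferase-like gene Tstd1 by 0.63 ± 0.12.

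Among the genes that fell, the gastrointestinal glutathione peroxidase Gpx2 (chromosome 12, 76792333 to 76795554) had a difference of -0.87 ± 0.18 (limma adjusted p = 0.0346), from 10.09 ± 0.52 to 9.21 ± 0.12. The kinase Pim1, a target of cytokine signalling (chromosome 17, 29490753 to 29496112), had a difference of -0.74 ± 0.12 (adjusted p = 0.000686), from 6.03 ± 0.23 to 5.28 ± 0.20, and all 4 Xiap-/- values lay below all 6 wild-type values for both genes. Pigr, the receptor that carries IgA across the epithelium (chromosome 1, 130826684 to 130852249), had a difference of -0.54 ± 0.13 (adjusted p = 0.0492), from 12.72 ± 0.32 to 12.18 ± 0.12. Glutathione reductase (Gsr) had a difference of -0.60 ± 0.12, the mitochondrial proline pathway enzyme Aldh4a1 -0.64 ± 0.12, the bacterial cell wall sensor Pglyrp1 -0.54 ± 0.11, the epithelial kinase Ptk6 -0.51 ± 0.12, the TGF-beta feedback gene Pmepa1 -0.49 ± 0.11 and the kinase Lrrk1 -0.45 ± 0.10. The largest differences of the antimicrobial lectins did not pass. Reg3g (chromosome 6, 78466269 to 78468872) lay at 12.74 ± 0.81 in wild-type and 11.41 ± 0.29 in Xiap-/- mice (difference -1.33 ± 0.31, adjusted p = 0.0655), and Reg3b (chromosome 6, 78370657 to 78373466) at 13.30 ± 0.70 and 12.12 ± 0.32 (-1.17 ± 0.27, adjusted p = 0.0599). Of the Paneth cell products named beforehand, Lyz1 had a difference of 0.24 ± 0.13, Ang4 0.53 ± 0.15, Defa24 0.02 ± 0.14 and Mmp7 0.00 ± 0.19 to the nearest hundredth, none passing. The cytokine Tnf was below the minimum mean and was not tested.

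**Figure D2:**
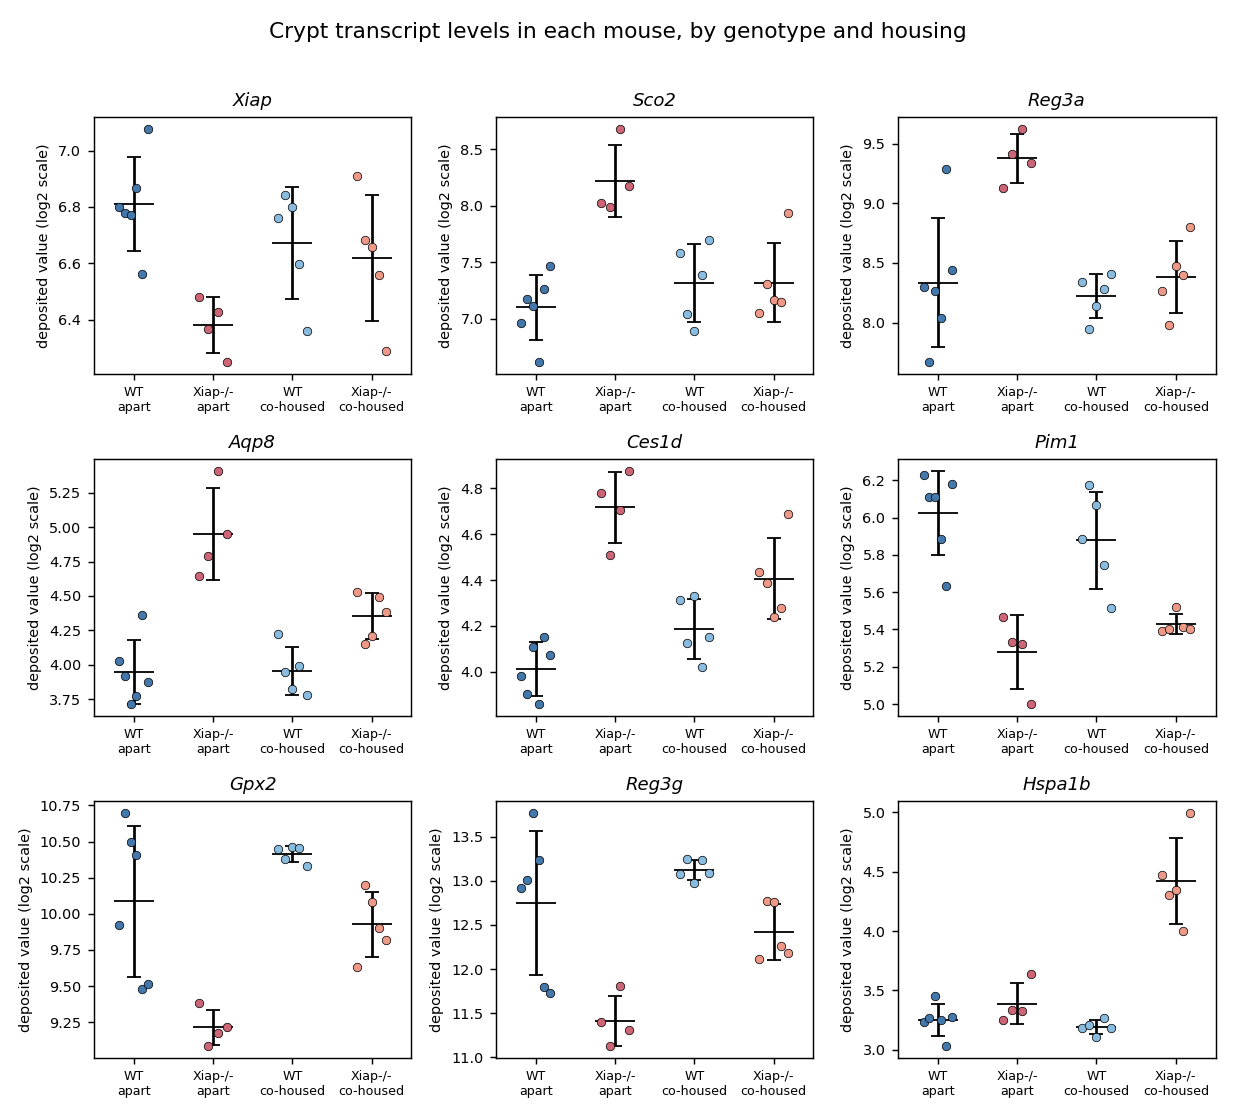
Levels of 9 genes (deposited values, log2 scale) in each mouse by genotype and housing. Points are mice, and bars are the group mean and SD. Sco2 and Aqp8 are highest in Xiap-/- mice housed apart (means 8.22 and 4.95), and Hspa1b is highest in co-housed Xiap-/- mice (mean 4.42).

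By gene group, camera called 10 of 22 lists in mice housed apart, and none of the 10 calls held with an estimated correlation (smallest adjusted p = 0.158 with an estimated correlation), while fry called 3. In simulated data whose list members vary together as in these libraries, camera at the preset correlation called a mean of 5.75 of the other 21 lists, to which no difference had been added, in this comparison. Xenobiotic metabolism genes were higher (mean 0.38, camera adjusted p = 2.59e-08, and adjusted p = 0.245 with an estimated correlation): of 17 measured, 3 rose (Ces1g by 0.49 ± 0.09, Aldh1a1 and Gsta1), 14 did not pass, and 8 rose when adjusted over the list alone. Targets of the fatty acid sensor PPAR were higher (mean 0.29, camera adjusted p = 3.86e-07, and adjusted p = 0.214 with an estimated correlation), with 0 of 14 passing over all genes by limma and 8 adjusted over the list alone. The fatty acid oxidation enzyme Acaa2 of that list had a difference of 0.43 ± 0.13 and its regulator Creb3l3 0.14 ± 0.11. Enteroendocrine markers were higher (mean 0.24, camera adjusted p = 7.38e-05, and adjusted p = 0.245 with an estimated correlation): Reg4 and the granule protein Chgb (0.47 ± 0.11) rose among 14, or 4 adjusted over the list alone. Tuft cell markers were higher (mean 0.21, camera adjusted p = 1.48e-04, and adjusted p = 0.214 with an estimated correlation), with 0 of 9 passing and 4 adjusted over the list alone. Ltc4s, which makes leukotrienes, had a difference of 0.32 ± 0.10.

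Paneth cell products were higher as a list (mean 0.21, camera adjusted p = 6.06e-04, and adjusted p = 0.499 with an estimated correlation), with 0 of 18 passing over all genes by limma. The 3 that passed adjusted over the list alone were the ribonuclease Ang4 and, outside antimicrobial defence, the fat-digesting proteins Pnliprp2 (0.75 ± 0.17) and Clps (0.72 ± 0.17). Pnliprp2 and Clps were chosen after their values were seen, and the alpha-defensins Defa24 and Defa30 (0.05 ± 0.14) differed by less than their errors. The acinar marker Cela1 was also higher, at 4.88 ± 0.12 in wild-type and 5.21 ± 0.24 in Xiap-/- mice, and did not pass. Cholesterol synthesis genes were lower (mean -0.21, camera adjusted p = 5.48e-07, and adjusted p = 0.158 with an estimated correlation): 2 of 18 fell, the sterol demethylase Cyp51 (-0.42 ± 0.09) and the epoxidase Sqle (-0.44 ± 0.10), and 9 adjusted over the list alone. Antigen presentation genes were lower (mean -0.23, camera adjusted p = 3.30e-04, and adjusted p = 0.330 with an estimated correlation), with 0 of 16 passing by limma and 1 adjusted over the list alone (the peptide loading protein Tapbp, chosen after its values were seen, -0.31 ± 0.09). The members with the highest means had differences of 0.15 ± 0.12 for B2m and -0.21 ± 0.11 for H2-K1. The 4 measured B and plasma cell markers, too few to test as a list, were all lower (mean -0.49), with Igha at 5.49 ± 0.63 in wild-type and 4.62 ± 0.11 in Xiap-/- mice and none passing. Mitochondrially encoded genes were lower (mean -0.28, camera adjusted p = 0.00169, and adjusted p = 0.345 with an estimated correlation), with 0 of 8 passing by limma and 0 adjusted over the list alone (mt-Cytb -0.35 ± 0.17 and mt-Nd1 -0.37 ± 0.17).

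Microbe-responsive epithelial genes were lower as a list (mean -0.39, camera adjusted p = 0.00483, and adjusted p = 0.302 with an estimated correlation), though of 14 measured 1 rose (Reg3a) and 1 fell (Pigr). Adjusted over the list alone, 3 rose and 6 fell, with Reg3b, Reg3g and Pigr among those that fell. The peroxide-making oxidase Duox2, chosen after its values were seen, also fell on that count (-1.08 ± 0.26). The list was not called on ranks (adjusted p = 0.108). Its mean lay at 7.50 and 7.36 in wild-type replicates 5 and 6, near the 7.28 to 7.54 of the Xiap-/- mice, and at 7.81 to 8.24 in the other 4 wild-type mice. TNF and NF-kB response genes were lower (mean -0.13, camera adjusted p = 0.0399, and adjusted p = 0.302 with an estimated correlation), with 0 of 9 passing by limma and 2 adjusted over the list alone. Their inhibitor Nfkbia had a difference of -0.35 ± 0.12 and the subunit Relb -0.08 ± 0.10. That call was lost without Xiap-/- replicate 1 (adjusted p = 0.0858), wild-type replicate 1 (0.0583) or wild-type replicate 3 (0.260). Goblet, stem cell, cell cycle, absorptive, interferon, cell death, ER stress, clock, immediate early and heat shock, T cell, ileal and proximal lists were not called. Single members of uncalled lists that rose were Adh1, an alcohol dehydrogenase (0.52 ± 0.12), and Ttr, a thyroid hormone carrier (0.42 ± 0.10).

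The number of genes by genotype in mice housed apart rested on single libraries. Of the 43, 6 passed without any one of the 20 libraries: Aqp8, Ces1d, Ces1g, Aadac, Pim1 and Gm3776. With each library left out in turn, Gpx2 passed in 12, Reg3a in 7 and Pigr in 2 of the 20 fits. Among libraries of Xiap-/- mice housed apart, the count was 9 without replicate 2, 10 without replicate 3 and 11 without replicate 4. Among those of wild-type mice housed apart, it was 13, 12, 28, 11, 697 and 67 without replicates 1, 2, 3, 4, 5 and 6, and it was 28 without co-housed Xiap-/- replicate 1. The depth proxy differed between these groups, and with it as a covariate the count was 1, while it was 25 without the deepest and the shallowest library. Sco2 did not pass without Xiap-/- replicate 3 (adjusted p = 0.0687), and its difference with the depth proxy as a covariate was 1.12 (adjusted p = 0.546). With that covariate, Reg3a moved from 1.04 to 0.50, Gsta1 from 0.91 to 0.55, Sgk1 from 0.82 to 0.52, Tstd1 from 0.63 to 0.41, Pglyrp1 from -0.54 to -0.35 and Pigr from -0.54 to -0.22 (limma adjusted p = 0.998 for each). Other genes that no longer passed shrank less or grew. Gsr moved from -0.60 to -0.50 (adjusted p = 0.926), Sqle from -0.44 to -0.46 (0.837) and Ptk6 from -0.51 to -0.60 (0.511). Ces1d, at 0.71, was the 1 gene that still passed (adjusted p = 0.0245), and Aqp8 stood at 0.84 (adjusted p = 0.0605).

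**Figure D3:**
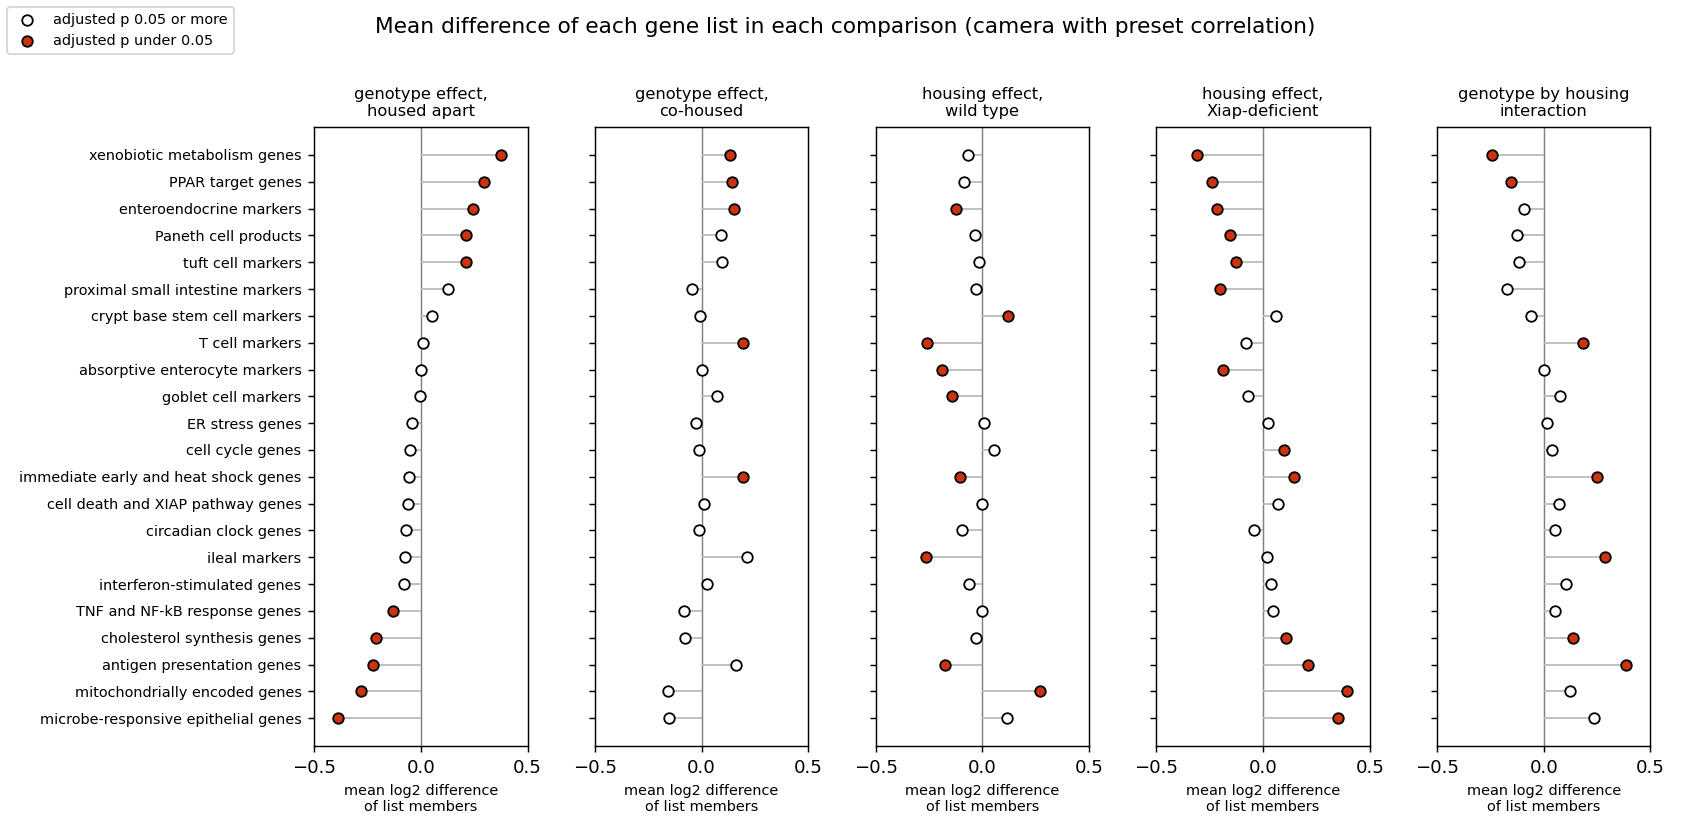
Mean log2 difference of the tested members of each of 22 gene lists (points) in the 5 comparisons. Filled points passed with camera at the preset correlation, and none of them passed with an estimated correlation. Xenobiotic metabolism genes have a mean of 0.38 by genotype in mice housed apart.

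In co-housed mice, the heat shock protein gene Hspa1b had the largest difference between the genotypes among the genes that passed. The comparison asks whether the genotypes differ once they have shared cages. Hspa1b, an inducible chaperone (chromosome 17, 34956436 to 34959238), rose by 1.23 ± 0.12 in Xiap-/- mice (limma adjusted p = 1.18e-07), from 3.19 ± 0.06 (SD, n = 5) to 4.42 ± 0.36 (n = 5), and all 5 Xiap-/- values lay above all 5 wild-type values. In mice housed apart its means were 3.25 (wild-type) and 3.39 (Xiap-/-), near the minimum mean for testing of 3.32. Hspa1b thus reached that minimum through the co-housed Xiap-/- mice. Banp, a DNA-binding nuclear protein, rose by 0.54 ± 0.10 (adjusted p = 0.0271), and Fry, a scaffold of NDR kinases, fell by 0.52 on the log2 scale (SE 0.10, adjusted p = 0.0271). These were the 3 genes that passed, while 1144 had an unadjusted p under 0.05 where chance gives 476. The number past the threshold depended on the model, with 143 when only these groups were fitted and 159 with array quality weights. The next smallest p-values, which did not pass, were those of the mitochondrial carrier homolog Mtch2 (-0.50 ± 0.10, adjusted p = 0.0635) and the tubulin Tubb2a (0.45 ± 0.09, adjusted p = 0.0789).

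None of the antimicrobial genes named beforehand passed between the co-housed genotypes. Reg3g lay at 13.12 ± 0.12 in wild-type and 12.42 ± 0.32 in Xiap-/- mice (difference -0.70 ± 0.31, limma adjusted p = 0.372), and Reg3b at 13.65 ± 0.18 and 12.90 ± 0.32 (-0.75 ± 0.27, adjusted p = 0.280). For both lectins all 5 Xiap-/- values nevertheless lay below all 5 wild-type values. The standard errors rest on the spread of all 4 groups, and the SD of Reg3g in wild-type mice housed apart was 0.81. The lack of a call therefore does not show that the difference was absent in co-housed mice. Lyz1 had a difference of 0.10 ± 0.12, Defa24 of 0.08 ± 0.13, Ang4 of 0.19 ± 0.14 and Mmp7 of -0.09 ± 0.18. Camera called 5 of 22 lists, all higher in Xiap-/- mice, none with an estimated correlation (smallest adjusted p = 0.405 with an estimated correlation), and fry called 1. The immediate early and heat shock list had a mean of 0.19 (camera adjusted p = 0.00354, and adjusted p = 0.405 with an estimated correlation), with Hspa1b the 1 of 13 that rose and 4 adjusted over the list alone. Its median was 0.03, with 5 of the 13 members below 0, and it was not called on ranks (adjusted p = 0.0984). T cell markers had a mean of 0.19 (camera adjusted p = 0.00354, and adjusted p = 0.672 with an estimated correlation), with 0 of 16 passing by limma and 0 adjusted over the list alone (Gzma 0.41 ± 0.25, Ccl5, a T cell chemokine, 0.41 ± 0.25). That call was lost without Xiap-/- replicate 3 (adjusted p = 0.111) or wild-type replicate 5 (0.0742).

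Enteroendocrine markers had a mean of 0.15 between the co-housed genotypes (camera adjusted p = 0.0335, and adjusted p = 0.672 with an estimated correlation), with 0 of 14 passing by limma and 0 adjusted over the list alone (Reg4 0.22 ± 0.13, the incretin Gip 0.15 ± 0.13). PPAR targets had a mean of 0.14 (camera adjusted p = 0.0406, and adjusted p = 0.672 with an estimated correlation), with 0 of 14 passing and 1 adjusted over the list alone (the lipase inhibitor Angptl4, chosen after its values were seen, 1.06 ± 0.23). Acaa2 had a difference of 0.17 ± 0.13. Xenobiotic metabolism genes had a mean of 0.14 (camera adjusted p = 0.0406, and adjusted p = 0.698 with an estimated correlation), with 0 of 17 passing and 0 adjusted over the list alone (the glutathione transferase Gstm3 0.14 ± 0.22, the glucuronosyltransferase Ugt2b34 0.26 ± 0.11). These 3 calls were each lost without Xiap-/- replicate 1 (adjusted p = 0.0894 for each) or replicate 5 (0.126, 0.0755 and 0.249) and without wild-type replicate 5 (0.0890, 0.0539 and 0.0539). The enteroendocrine and PPAR calls were also lost without wild-type replicate 2 (0.0749 and 0.151), and the PPAR and xenobiotic calls without Xiap-/- replicate 3 (0.0910 and 0.0560) or wild-type replicate 3 (0.0620 and 0.110). With no low-value filter all 3 calls were lost (enteroendocrine and PPAR adjusted p = 0.0590, xenobiotic 0.0544), and the PPAR call also on ranks (0.0984). The other 17 lists were not called.

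Leaving out libraries moved the co-housed counts. The 3 genes became 1 without Xiap-/- replicate 1 or 4 or wild-type replicate 3, 6 without Xiap-/- replicate 2 or wild-type replicate 1, and 5 or 12 without replicate 3 or 4 of the wild-type mice housed apart. Hspa1b passed without any one of the 20 libraries. Banp had its highest adjusted p, 0.115, without Xiap-/- replicate 1, and Fry 0.111 without wild-type replicate 3. The 5 lists became 2 without Xiap-/- replicate 1 or wild-type replicate 5, 3 without Xiap-/- replicate 3 or wild-type replicate 3, 8 without wild-type replicate 4, and 9 without Xiap-/- replicate 2 or 4.

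Across 9521 genes, the genotype differences in the housings had a Pearson r of 0.373 and a Spearman rho of 0.359. Genes are not independent replicates, and a jackknife over libraries gave a standard error of 0.171 for r. Of the 43 genes that passed in mice housed apart, 36 had the same sign in co-housed mice and 0 passed there by limma. Their median difference along the direction housed apart was 0.52 in mice housed apart, where they were selected, and 0.15 in co-housed mice. Sco2 had a level of 7.32 ± 0.34 (SD, n = 5) in co-housed wild-type and 7.32 ± 0.35 (n = 5) in co-housed Xiap-/- mice, and Aqp8 had 3.95 ± 0.17 and 4.35 ± 0.17. The test of the difference between the genotype differences was the interaction, given last.

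**Figure D4:**
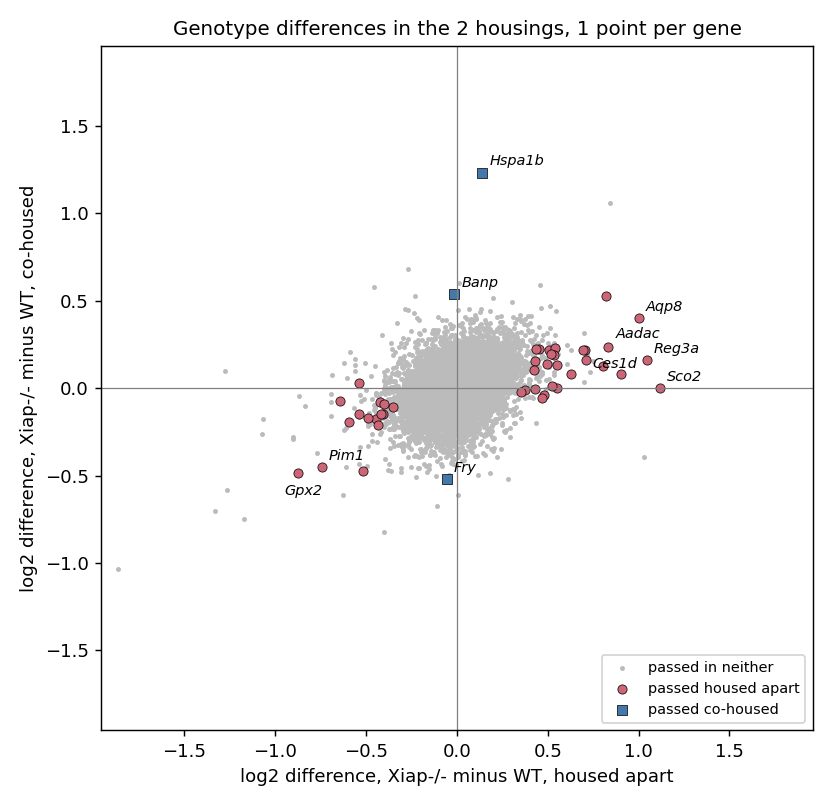
Genotype difference (Xiap-/- minus wild-type, log2) of each of 9521 genes in mice housed apart (horizontal) and co-housed (vertical). Circles passed in mice housed apart, and squares passed in co-housed mice. Sco2 lies at 1.12 and Hspa1b at 1.23 on their own axes, and 36 of the 43 circles have the same sign on both axes.

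In wild-type mice, living with Xiap-/- mice went with no single gene past the threshold. The comparison asks what co-housing changes in wild-type crypts. Of 9521 genes, 0 passed by limma, with 969 at an unadjusted p under 0.05 where chance gives 476. The smallest p-values were those of the clock repressor Nr1d1 (chromosome 11, 98767932 to 98775333; -0.69 ± 0.13, adjusted p = 0.0612), the citrate carrier Slc13a2 (-0.65 ± 0.13, adjusted p = 0.0612), the stress-responsive gene Ndrg1 (-0.50 ± 0.10, adjusted p = 0.0612), Unc5cl, an epithelial activator of NF-kB (0.52 ± 0.11, adjusted p = 0.0773), and the nuclease Dnase1 (-0.53 ± 0.11, adjusted p = 0.0900). The count became 66 without wild-type replicate 4 of the mice housed apart. Reg3g had a difference of 0.38 ± 0.29, Reg3b of 0.35 ± 0.26, Lyz1 of -0.05 ± 0.12, Ang4 of -0.02 ± 0.14, Defa24 of -0.07 ± 0.13, Mmp7 of 0.07 ± 0.17 and Xiap of -0.14 ± 0.10.

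Camera called 9 of 22 lists by housing in wild-type mice, none with an estimated correlation (smallest adjusted p = 0.168 with an estimated correlation), and fry called 1. Over all genes, 0 members of these lists passed by limma. T cell markers were lower in co-housed mice (mean -0.26 over 16 genes, camera adjusted p = 1.94e-06, and adjusted p = 0.372 with an estimated correlation), with 0 adjusted over the list alone (Gzma -0.57 ± 0.24). Absorptive enterocyte markers were lower (mean -0.19 over 24 genes, camera adjusted p = 2.47e-06, and adjusted p = 0.419 with an estimated correlation), with 4 adjusted over the list alone. These were the sugar carriers Slc2a5 (-0.44 ± 0.12) and Slc5a1 (-0.37 ± 0.12), the peptide carrier Slc15a1 (-0.41 ± 0.14) and Dgat1, an enzyme of fat synthesis (-0.29 ± 0.10), all chosen after their values were seen. The members with the highest means, the fatty acid binding protein Fabp2 (-0.22 ± 0.14) and the apolipoprotein Apoa1 (-0.20 ± 0.13), were not among them. Goblet cell markers were lower (mean -0.14 over 15 genes, camera adjusted p = 3.62e-04, and adjusted p = 0.168 with an estimated correlation), with 3 adjusted over the list alone (among them the trefoil peptide Tff3, -0.36 ± 0.12). Antigen presentation genes were lower (mean -0.17 over 16 genes, camera adjusted p = 3.62e-04, and adjusted p = 0.418 with an estimated correlation), with 0 adjusted over the list alone (H2-K1 -0.27 ± 0.10). Of lists too small to test, Igha lay at 5.49 ± 0.63 housed apart and 5.21 ± 0.63 co-housed. The blood marker Hbb-bs lay at 4.55 ± 0.29 and 4.07 ± 0.22, and neither gene passed.

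Ileal markers were lower in co-housed wild-type mice (mean -0.27 over 6 genes, camera adjusted p = 0.00343, and adjusted p = 0.372 with an estimated correlation), with 2 adjusted over the list alone (Fabp6 -0.55 ± 0.19, Slc51a -0.33 ± 0.10), a call lost without co-housed wild-type replicate 5 (adjusted p = 0.0935). Immediate early and heat shock genes were lower (mean -0.10 over 13 genes, camera adjusted p = 0.00984, and adjusted p = 0.372 with an estimated correlation), with 0 adjusted over the list alone (the transcription factor Junb -0.34 ± 0.11). Enteroendocrine markers were lower (mean -0.12 over 14 genes, camera adjusted p = 0.0294, and adjusted p = 0.612 with an estimated correlation), with 0 adjusted over the list alone (Gip -0.16 ± 0.12). That call was lost without replicate 2 (adjusted p = 0.0562) or 5 (0.155) of the wild-type mice housed apart and without replicate 2 (0.144) or 5 (0.140) of the co-housed ones, and with no low-value filter (0.107). Mitochondrially encoded genes were higher (mean 0.27 over 8 genes, camera adjusted p = 2.95e-04, and adjusted p = 0.372 with an estimated correlation), with 0 adjusted over the list alone (mt-Nd1 0.31 ± 0.16). Crypt base stem cell markers were higher (mean 0.12 over 16 genes, camera adjusted p = 0.00114, and adjusted p = 0.372 with an estimated correlation), with 0 adjusted over the list alone (the pentaspan protein Prom1 0.18 ± 0.10, the ion carrier Slc12a2 0.08 ± 0.11). Clock genes were not called as a list (mean -0.10, camera adjusted p = 0.279), and adjusted over the list alone 1 rose and 4 fell among 12.

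In Xiap-/- mice, living with wild-type mice went with more transcript of the chaperone genes Hspa1b and Hsph1 and less of Dnase1 and Adh4. The comparison asks what co-housing changes in Xiap-/- crypts. Of 9521 genes, 5 rose and 9 fell. Hspa1b rose by 1.03 ± 0.12 (limma adjusted p = 2.33e-05), from 3.39 ± 0.17 (SD, n = 4) to 4.42 ± 0.36 (n = 5), and the chaperone Hsph1 (chromosome 5, 149614287 to 149636376) rose by 0.92 ± 0.15 (adjusted p = 0.00632), from 6.73 ± 0.17 to 7.65 ± 0.29. For both, all 5 co-housed values lay above all 4 values of mice housed apart. The pore-forming gasdermin Gsdmc4 rose by 0.70 ± 0.13 (adjusted p = 0.0146), Banp by 0.53 ± 0.11 and the epithelial 14-3-3 protein Sfn by 0.45 ± 0.10.

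Among the 9 genes that passed and were lower in co-housed Xiap-/- mice, Dnase1 fell most (-0.71 ± 0.12, limma adjusted p = 0.00829), from 9.56 ± 0.27 to 8.85 ± 0.11. The alcohol dehydrogenase Adh4 had a difference of -0.53 ± 0.10 (adjusted p = 0.00951), the fatty acid transporter Cd36 -0.62 ± 0.13, Tstd1 -0.64 ± 0.13, the retinal reductase Dhrs4 -0.54 ± 0.11, the EGF receptor inhibitor Errfi1 -0.52 ± 0.11, Ltc4s -0.52 ± 0.11, the steroid reductase Srd5a1 -0.43 ± 0.09 and the procollagen protease Bmp1 -0.43 ± 0.09. The antimicrobial lectins did not pass: Reg3g had a difference of 1.01 ± 0.33 (adjusted p = 0.267) and Reg3b of 0.78 ± 0.28 (adjusted p = 0.321). For Reg3g all 5 co-housed values lay above all 4 values of mice housed apart, while the values of Reg3b overlapped. These errors also draw on wild-type mice housed apart, in which the SD of Reg3g was 0.81, against 0.29 and 0.32 in the groups compared. Ang4 had a difference of -0.36 ± 0.15, Lyz1 of -0.19 ± 0.13, Defa24 of -0.01 ± 0.14, Mmp7 of -0.02 ± 0.19 and Xiap of 0.24 ± 0.11.

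Camera called 13 of 22 lists by housing in Xiap-/- mice, none with an estimated correlation (smallest adjusted p = 0.272 with an estimated correlation), and fry called 0. Xenobiotic metabolism genes were lower (mean -0.31, camera adjusted p = 2.27e-06, and adjusted p = 0.272 with an estimated correlation), with 0 of 17 passing by limma and 7 adjusted over the list alone. The member with the highest mean, Gstm3 (-0.49 ± 0.23), was not among the 7. PPAR targets were lower (mean -0.24, camera adjusted p = 3.43e-06, and adjusted p = 0.272 with an estimated correlation), with 0 of 14 passing and 5 adjusted over the list alone (among them Acaa2, -0.39 ± 0.14). Absorptive enterocyte markers were lower (mean -0.19, camera adjusted p = 5.38e-05, and adjusted p = 0.379 with an estimated correlation), with 0 of 24 passing and 2 adjusted over the list alone (the apolipoprotein Apob -0.49 ± 0.14 and the retinol carrier Rbp2 -0.46 ± 0.12, both chosen after their values were seen). Fabp2, the member with the highest mean, had a difference of -0.13 ± 0.15. Enteroendocrine markers were lower (mean -0.22, camera adjusted p = 1.11e-04, and adjusted p = 0.272 with an estimated correlation), with 0 of 14 passing and 4 adjusted over the list alone (among them Reg4, -0.56 ± 0.14). Mitochondrially encoded genes were higher (mean 0.39, camera adjusted p = 4.12e-06, and adjusted p = 0.272 with an estimated correlation), with 0 of 8 passing and 4 adjusted over the list alone (among them mt-Cytb, 0.46 ± 0.18). Microbe-responsive genes were higher (mean 0.35, camera adjusted p = 0.00135, and adjusted p = 0.272 with an estimated correlation), with 0 of 14 passing and, adjusted over the list alone, 6 higher and 2 lower. Among the higher were Pigr (0.46 ± 0.13), Reg3b, Reg3g and, chosen after its values were seen, Duox2 (1.28 ± 0.27), and the lower ones were Ang4 and, also chosen afterwards, Reg3a (-0.99 ± 0.23). The microbe-responsive call was not made on ranks (adjusted p = 0.0599).

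The remaining 7 calls by housing in Xiap-/- mice rested on single libraries. Lower were Paneth cell products (mean -0.16, camera adjusted p = 0.00559, and adjusted p = 0.526 with an estimated correlation), with 0 of 18 passing by limma and 2 adjusted over the list alone, a call lost without replicate 1 (adjusted p = 0.136) or 2 (0.122) housed apart or co-housed replicate 4 (0.378). Also lower were proximal intestine markers (mean -0.20, camera adjusted p = 0.0159, and adjusted p = 0.272 with an estimated correlation), with 0 of 9 passing and 3 adjusted over the list alone, a call lost without replicate 3 housed apart (adjusted p = 0.120), with no low-value filter (0.0558) and on ranks (0.155). Tuft cell markers were lower (mean -0.13, camera adjusted p = 0.0175, and adjusted p = 0.335 with an estimated correlation), with Ltc4s the 1 of 9 that fell and 1 adjusted over the list alone, a call lost without replicate 2 housed apart (adjusted p = 0.0874) or co-housed replicate 2 (0.0993) or 3 (0.0808). Antigen presentation genes were higher (mean 0.21, camera adjusted p = 0.00530, and adjusted p = 0.379 with an estimated correlation), with 0 of 16 passing and 0 adjusted over the list alone, a call lost without replicate 1 (adjusted p = 0.0562) or 2 (0.117) housed apart. All 4 B and plasma cell markers, not tested as a list, were higher as well (mean 0.38, Igha 0.55 ± 0.35), none passing. Cell cycle genes were higher (mean 0.10, camera adjusted p = 0.00530, and adjusted p = 0.343 with an estimated correlation), with 0 of 22 passing and 1 adjusted over the list alone (the replication helicase subunit Mcm6, chosen after its values were seen, 0.31 ± 0.09). The member with the highest mean, the DNA topoisomerase Top2a, had a difference of 0.14 ± 0.13, and the call was lost without replicate 3 housed apart (adjusted p = 0.0895). Cholesterol synthesis genes were higher (mean 0.11, camera adjusted p = 0.00530, and adjusted p = 0.272 with an estimated correlation), with 0 of 18 passing and 1 adjusted over the list alone, a call lost without co-housed replicate 3 (adjusted p = 0.0728). Immediate early and heat shock genes were higher (mean 0.15, median 0.00 to the nearest hundredth, camera adjusted p = 0.0379, and adjusted p = 0.286 with an estimated correlation), with Hspa1b and Hsph1 the 2 of 13 that rose and 3 adjusted over the list alone. That call was lost without replicate 1 (adjusted p = 0.205) or 4 (0.0553) housed apart or co-housed replicate 3 (0.168), and on ranks (0.598).

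Of the 14 genes by housing in Xiap-/- mice, Hspa1b passed without any one of the 20 libraries. Without Xiap-/- replicates 1, 2, 3 and 4 of the mice housed apart the count was 23, 6, 2 and 6, and without co-housed Xiap-/- replicates 1, 2, 3 and 4 it was 5, 2, 8 and 4. Without replicates 2, 4 and 5 of the wild-type mice housed apart, which enter the shared estimate of spread, it was 23, 22 and 64. The depth proxy differed between these groups too, and with it as a covariate the count was 1, while it was 5 without the deepest and the shallowest library. The gene that passed with the covariate was Hspa1b (1.03, limma adjusted p = 5.85e-04), and the differences of genes that no longer passed were 0.77 for Hsph1 (adjusted p = 0.117), 0.66 for Gsdmc4 (0.212), 0.52 for Banp (0.212), -0.64 for Dnase1 (0.117) and -0.49 for Adh4 (0.144). The housing differences of the genotypes had a Pearson r of 0.250 across genes and a Spearman rho of 0.228 (jackknife standard error of r 0.30), and 11 of the 14 genes had the same sign in wild-type mice.

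The interaction asks whether the genotype difference itself changed with housing, and 1 gene passed. Hspa1b had a genotype difference larger by 1.10 ± 0.17 in co-housed mice than in mice housed apart (limma adjusted p = 0.00254), and it passed without any one of the 20 libraries. With the depth proxy as a covariate its difference was 1.10 as well, but it did not pass (adjusted p = 0.0620). The next smallest p-values, all at an adjusted p of 0.336, were those of Gm3776 (-0.68 ± 0.16), a predicted gene, the exoribonuclease Xrn2 (-0.57 ± 0.13), the fatty acid elongase Elovl5 (0.51 ± 0.12) and Mtch2 (-0.61 ± 0.15). For Reg3g the interaction was 0.63 ± 0.44, for Reg3b 0.43 ± 0.38, for Ang4 -0.34 ± 0.20, for Lyz1 -0.14 ± 0.18, for Defa24 0.06 ± 0.19, for Mmp7 -0.09 ± 0.26 and for Xiap 0.37 ± 0.15. All 43 genes that passed by genotype in mice housed apart had an interaction of the opposite sign (median -0.39 along their direction), and 0 of them passed the interaction by limma, which had 671 genes at an unadjusted p under 0.05 where chance gives 476. That median is drawn away from 0 by the selection of the genes in the same libraries.

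By gene group, camera called 7 of 22 lists in the interaction, none with an estimated correlation (smallest adjusted p = 0.130 with an estimated correlation), and fry called 1. Antigen presentation genes had a mean of 0.38 (camera adjusted p = 9.67e-07, and adjusted p = 0.416 with an estimated correlation), with 0 of 16 passing by limma and 0 adjusted over the list alone (H2-K1 0.25 ± 0.15). All 4 B and plasma cell markers, not tested as a list, had a difference above 0 too (mean 0.54, Igha 0.83 ± 0.47), none passing. Immediate early and heat shock genes had a mean of 0.25 (camera adjusted p = 1.38e-04, and adjusted p = 0.130 with an estimated correlation), with Hspa1b the 1 of 13 passing and 2 adjusted over the list alone. Xenobiotic metabolism genes had a mean of -0.24 (camera adjusted p = 0.00182, and adjusted p = 0.499 with an estimated correlation), with 0 of 17 passing and 0 adjusted over the list alone (Gstm3 -0.47 ± 0.31). Cholesterol synthesis genes had a mean of 0.14 (camera adjusted p = 0.00494, and adjusted p = 0.416 with an estimated correlation), with 0 of 18 passing and 0 adjusted over the list alone, a call lost without co-housed Xiap-/- replicate 3 (adjusted p = 0.0504).

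T cell markers had a mean of 0.18 in the interaction (camera adjusted p = 0.0141, and adjusted p = 0.642 with an estimated correlation), with 0 of 16 passing by limma and 0 adjusted over the list alone (Gzma 0.51 ± 0.36). Of mice housed apart, that call was lost without Xiap-/- replicate 1 (adjusted p = 0.0579) or 2 (0.202) and wild-type replicate 1 (0.0979) or 5 (0.115). Of co-housed mice, it was lost without Xiap-/- replicate 3 (0.144) or 4 (0.0630) and wild-type replicate 5 (0.115). PPAR targets had a mean of -0.15 (camera adjusted p = 0.0141, and adjusted p = 0.499 with an estimated correlation), with 0 of 14 passing and 0 adjusted over the list alone (Acaa2 -0.26 ± 0.18). That call was lost without Xiap-/- replicate 3 (adjusted p = 0.126) or wild-type replicate 4 (0.126) housed apart and without co-housed Xiap-/- replicate 2 (0.0693) or wild-type replicate 4 (0.0503). Ileal markers had a mean of 0.29 (camera adjusted p = 0.0170, and adjusted p = 0.498 with an estimated correlation), with 0 of 6 passing and 1 adjusted over the list alone (Slc51a 0.43 ± 0.15), while Fabp6 had a difference of 0.67 ± 0.28. Their call was lost without wild-type replicate 5 housed apart (adjusted p = 0.115), co-housed Xiap-/- replicate 3 (0.0646) or wild-type replicate 5 (0.0950), with no low-value filter (0.149), and on ranks (0.108). The number of lists was 11 without Xiap-/- replicate 3 or 4 housed apart or co-housed Xiap-/- replicate 5.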

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

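The tests of depth, villus tissue, time of day, handling stress and a linked variant were chosen after the results they concern had been seen, and the splits of the libraries were planned.

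The genes by genotype in mice housed apart were weighed first. Of 100 splits of these 10 libraries, 8 called at least the real 43 genes, so chance cannot be excluded, and the highest other split, wild-type replicates 1, 2, 4 and 6 against the rest, called 1363, which points to a structure among the samples: these 4 have the highest plateau offsets of the 10 (0.688 to 3.77 in thousandths, others up to 0.450), so this split follows the depth proxy by offset, though by the share of rare genes replicate 1 (7.55%) stands above replicate 3 (7.17%). More villus tissue in the Xiap-/- preparations is not seen in the 24 absorptive enterocyte markers, whose median difference was 0.0366 (SD 0.209 over the markers) and whose list was not called. The genes called higher had a median of 0.538, but they were selected for their differences in the same libraries. A comparison with them therefore cannot decide, and a smaller excess of villus tissue was not tested. A difference in depth stays open: with the proxy as a covariate, the mean difference of the 43 genes along their direction was 0.431 ± 0.096 (SE), against 0.585 ± 0.083 without it, 1 call was left, with smaller differences and a wider error, and 14 of 100 rearrangements with depth and chance alone, the real order included, gave a mean as large (median 0.295) for 43 genes selected in the same way. Another time of collection stays open, since the difference between the clock gene arms was 0.243 ± 0.125 (exact permutation p = 0.167, adjusted p = 0.222 over 4 comparisons), and so do cage and genotype, which the design does not separate in mice housed apart.

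Heat shock genes in co-housed Xiap-/- mice were weighed next. The mean of Hspa1b, Hsph1, Dnajb1 and Hspa8 was 7.08 ± 0.17 (SD, n = 5) there, against 6.47 ± 0.10 in co-housed wild-type mice, 6.45 ± 0.09 in Xiap-/- mice and 6.47 ± 0.13 in wild-type mice housed apart. Hspa1a and Hspb1 of the same list lay below the minimum mean and were not tested. Handling stress that also raises immediate early genes is not seen in 9 such genes, whose median difference between the co-housed genotypes was -0.0047 (SD 0.056 over the genes). The heat shock genes had a median of 0.463, a size that their selection may have raised, so the comparison with it cannot decide. A variant linked to the Xiap locus that acts in either housing is argued against by the genotype by housing difference of 0.624 ± 0.116, with -0.0212 between the genotypes housed apart. The heat shock genes were picked after Hspa1b and Hsph1 had passed, which may enlarge their differences, the 0.463 and the 0.624 among them. Depth is argued against by the plateau offset, which hardly differed between the co-housed genotypes (0.111 in thousandths, exact permutation p = 0.905). The co-housed difference was 0.601 ± 0.081 with the proxy as a covariate, against 0.603 ± 0.081 without it. That covariate could hardly move it, since these groups did not differ in the offset. Heat at collection without an immediate early response, the day or cage of the mice, and an effect of Xiap loss in shared cages were not tested and stay open.

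The clock genes of wild-type mice were weighed last. By housing, the arm of Arntl, Clock and Npas2 stood 0.20 higher and the arm of Nr1d1, Nr1d2, Dbp, Tef, Per1 and Cry2 had a mean difference of -0.34 in co-housed mice, so that the difference between the arms was 0.531 ± 0.117 (exact permutation p = 0.00649, adjusted p = 0.0260 over 4 comparisons). The arms were tested after the clock genes of these libraries, Nr1d1 among them, had been seen. These p-values do not account for that choice. Opposite movement of the arms is what collection at another time of day would give, so that explanation may hold, and a change of the clock by shared microbes stays open as well. By housing in Xiap-/- mice the arm difference was 0.197 ± 0.130 (exact permutation p = 0.143, adjusted p = 0.222), and between the co-housed genotypes -0.0911 ± 0.122 (exact permutation p = 0.349, adjusted p = 0.349), neither passing. With the depth proxy as a covariate the arm difference was 0.587 ± 0.123, against 0.531 without it, so the proxy did not account for it. Because the arms were chosen after their values were seen, and the same choice was not made under depth alone, depth is not excluded.

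For the other comparisons, what the splits say of chance differed. Between the co-housed genotypes, 1 of 100 splits, the real one, called 3 genes or more (highest other 1). Between the housings of Xiap-/- mice, 1 of 100, the real one, called 14 or more (highest other 4). The other splits tried thus did not reach these counts, but they treat mice as exchangeable, though cages are not named. Both counts also moved with single libraries and with the depth proxy as a covariate. Between the housings of wild-type mice, the splits test nothing, because with 0 real genes all 100 call as many by construction, and the highest other called 194, which points to a structure within these mice that their housing does not name. For the interaction, 8 of 100 reassignments of housing within genotype called at least the real 1 gene, and the highest other called 36, so chance cannot be excluded for that count.

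By the interaction test, Hspa1b (1.10) passed. Camera at the preset correlation called antigen presentation genes (0.38), ileal markers (0.29), the immediate early and heat shock list (0.25), xenobiotic metabolism genes (-0.24), T cell markers (0.18), PPAR targets (-0.15) and cholesterol synthesis genes (0.14). These list calls were lost with an estimated correlation. In simulated data that keep the correlation between genes, the preset correlation called a mean of 4.40 lists with no shift in this comparison. With the depth proxy as a covariate, Hspa1b did not pass (limma adjusted p = 0.0620).

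Single libraries stood far from the rest of their group in 25 of 316 group values checked, where chance gives about 15.8, and 5 of these were in Xiap-/- replicate 3 housed apart. In Xiap-/- mice housed apart, replicate 3 had Tstd1 at 8.20 (others 7.80 to 7.87), Reg3b at 12.59 (11.91 to 12.02), and list means of 8.05 for goblet cell markers (7.88 to 7.89), 5.76 for interferon-stimulated genes (5.20 to 5.23) and 8.44 for proximal intestine markers (8.11 to 8.14). Replicate 2 of that group had Reg4 at 8.75 (8.37 to 8.41) and Sfn at 7.62 (7.82 to 7.86), and replicate 4 had Fry at 3.54 (3.41 to 3.42). In wild-type mice housed apart, replicate 3 had list means of 5.58 for interferon-stimulated genes (5.37 to 5.43) and 6.71 for ER stress genes (6.55 to 6.60), and replicate 5 had 14.9% of rare genes above their plateau (4.58% to 7.55%).

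In co-housed Xiap-/- mice, replicate 2 had Tubb2a at 4.05 (others 4.54 to 4.59), Errfi1 at 4.80 (5.14 to 5.27), absorptive enterocyte markers at a list mean of 9.86 (10.11 to 10.15) and a plateau offset of 2.70 in thousandths (-0.919 to -0.245). Replicate 4 had Lyz1 at 11.69 (12.09 to 12.24), Ang4 at 8.73 (9.12 to 9.28) and cell death genes at a list mean of 6.27 (6.23 to 6.23). Replicate 5 had Pigr at 12.48 (12.66 to 12.71) and Mtch2 at 4.68 (4.90 to 4.97), replicate 3 had Pim1 at 5.52 (5.39 to 5.41), and replicate 1 had Ndrg1 at 8.15 (7.76 to 7.86). In co-housed wild-type mice, replicate 3 had Fry at 3.98 (3.87 to 3.89), replicate 4 had Ces1g at 3.38 (3.21 to 3.24) and replicate 5 had Lyz1 at 11.54 (others up to 12.12).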

How the results depend on the processing

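A pseudocount of 1, ordinary empirical Bayes moderation, the depth proxy as a covariate and the fit without the deepest and the shallowest library (Xiap-/- replicate 2 and wild-type replicate 6, both housed apart) were chosen after seeing the data, and the other alternatives were planned. The cause of a change was not tested except where fewer genes or fewer samples give it. No result reversed. Of 1356 values of the 43 named results that passed, 985 stayed past the threshold and 371 lost it, and of 1456 values of the 46 that did not pass, 59 passed and 34 changed sign without passing.

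For genotype in mice housed apart (43 genes), the count was 25 with a mean of at least 50, 385 with array quality weights, 350 with the replicate number as a block, 12 with only these groups, 66 with ordinary moderation, 25 without the deepest and the shallowest library and 1 with the depth proxy as a covariate. For genotype in co-housed mice (3 genes), it was 10 with no filter, 0 by limma with a mean of at least 50, 159 with weights, 143 with only these groups, 8 with the depth proxy and 1 without that pair of libraries. At a mean of at least 50 the 3 genes, Hspa1b, Banp and Fry, are no longer tested, so that 0 says nothing of them. For housing in wild-type mice (0 genes by limma, 969 at an unadjusted p under 0.05), it was 5 with no filter and 5 with weights. For housing in Xiap-/- mice (14 genes), it was 8 with a mean of at least 50, 224 with weights, 189 with the block, 167 with only these groups, 22 with ordinary moderation, 5 without that pair of libraries and 1 with the depth proxy. For the interaction (1 gene), it was 0 with a mean of at least 50, where Hspa1b is no longer tested, 4 with weights, 10 with the block and 0 by limma with the depth proxy, where the difference of Hspa1b stayed at 1.10 (adjusted p = 0.0620). With an estimated correlation camera called 0 lists in each of the 5 comparisons, and for genotype in co-housed mice 3 lists on ranks and 2 with no filter against 5.

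Nothing in the labels says that equal replicate numbers mark mice kept or handled together, and the residuals of libraries with the same number had a mean correlation of 0.0359 (27 pairs, -0.42 to 0.36, 10 of them above 0.1). The blocked counts therefore assume a pairing that the values do not show. With the block, the immediate early and heat shock call by housing in Xiap-/- mice was lost (camera adjusted p = 0.0585).

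Leaving out each library in turn gave 9 to 697 genes for genotype in mice housed apart, 1 to 12 for genotype in co-housed mice, 0 to 66 for housing in wild-type mice, 2 to 64 for housing in Xiap-/- mice and 1 to 1 for the interaction. The number of lists ranged from 9 to 13, 2 to 9, 7 to 11, 11 to 13 and 5 to 11 in the same order. The correlation of genotype differences between housings ranged from 0.27 to 0.44 and that of housing differences between genotypes from 0.06 to 0.33. The Xiap difference ranged from -0.48 to -0.37 in mice housed apart and from -0.132 to 0.0290 in co-housed mice, where it changed sign without co-housed Xiap-/- replicate 5. Counts on recovered reads, their totals and a depth covariate from them could not be run, since the values hold no counts. Depth therefore limits what can be said of rare genes.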

Other observations

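None of the values here was planned as a comparison, and the tests of shared libraries and of covariation within groups were chosen after seeing the data. Some genes, picked after their values were seen, parted replicates 5 and 6 of the wild-type mice housed apart from the other 4, and no test was made of this. Reg3g lay at 11.80 and 11.73 in replicates 5 and 6 and between 12.92 and 13.77 in replicates 1 to 4. In the same order of mice, Duox2 lay at 5.18 and 5.19 and between 6.23 and 6.64, the acute phase gene Saa1 at 4.86 and 5.69 and between 6.84 and 8.12, the IgA heavy chain Igha at 4.61 and 4.92 and between 5.49 and 6.31, and the MHC class II chain H2-Aa at 7.88 and 7.14 and between 8.48 and 8.98. The mean of the antigen presentation list did not part them, at 8.58 and 8.28 against 8.57 to 8.93. In Xiap-/- mice housed apart, Reg3g ranged from 11.13 to 11.81 and Duox2 from 4.78 to 5.12. The library with 697 genes by genotype when left out was wild-type replicate 5.

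Members of many gene lists, though not all, moved together between mice of the same group. Within groups, the mean correlation between members was 0.662 for T cell markers, 0.644 for Paneth cell products, 0.670 for mitochondrially encoded genes, 0.594 for absorptive enterocyte markers, 0.570 for xenobiotic metabolism genes and 0.395 for interferon-stimulated genes, each above all 1000 random lists of equal size. It was 0.197 for microbe-responsive genes, above 99.6% of random lists, and -0.0053 for cell death genes, above 41%. For goblet cell markers it was 0.066 (above 81.7%), for immediate early and heat shock genes 0.094 (94.8%) and for proximal intestine markers 0.185 (94.8%). These correlations are across genes and mice within groups, and list members are not independent.

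Genotype in mice housed apart and housing in Xiap-/- mice share the 4 Xiap-/- libraries housed apart. Their differences correlated at r = -0.709 across genes, where simulated data with no effect gave -0.577 (-0.597 to -0.554) from the shared libraries alone and permuted residuals gave -0.836 to 0.237. With the shared libraries parted into pairs, r ranged from -0.521 to -0.281 over 6 values. Adh4 (0.43 and -0.53), Bmp1 (0.35 and -0.43), Dhrs4 (0.48 and -0.54) and Tstd1 (0.63 and -0.64) rose in the first and fell in the second.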
